A study of Mus musculus and synthetic construct with 49 samples.

How the data were processed

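Pooled CRISPR-Cas9 knockout screens were read out by sequencing sgRNAs in mouse N2A neuroblastoma cells that carried 1 of 3 fluorescent reporters. Per the labels, the genome-wide mouse Brie library of 78637 sgRNAs was delivered to 80000000 cells at a multiplicity of infection of 0.3, about 300 cells per sgRNA. Infected cells were selected with 2.5 µg/ml puromycin, and the splicing reporters were induced with 1 µg/ml doxycycline. The Shank2 and Mef2d reporters each carry a microexon, an exon of very few nucleotides used mainly in neurons, and were sorted by the EGFP:mCherry ratio. The third line carries EGFP on the endogenous Srrm4 protein and was sorted by EGFP. Sorted samples hold the 2% of cells with the highest or lowest signal, 300000 to 500000 cells, and Mef2d cells were also sorted into 30% gates. The labels give each sample a number after the letter T without a unit, and do not say which fluorophore reports microexon inclusion.

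The deposited values are raw read counts per sgRNA, not normalised, with 1 column per library. Per the labels, the authors amplified the sgRNAs in 25 and then 10 cycles of PCR, demultiplexed the reads with bcl2fastq and processed them with MAGeCK 0.5.6. The genome build used by the authors is not given in the sources used here. Gene names, neighbours and chromosomes were taken from the RefSeq annotation of the mouse assembly GRCm38.p6, in which 56 of the gene names could not be placed. The tables held 79633 sgRNAs, of which 78633 named 1 of 19674 genes and 1000 named no gene. The sgRNAs without a gene name took 1.25% of the plasmid library's counts (exact 95% interval 1.249 to 1.256) and up to 1.98% of a cell library's, and were not summed into any gene. Counts were read as the tables give them, and PCR reads carried no molecular identifiers, so intervals and floors below cover counting error only.

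Counts were summed per gene for the 19663 genes with at least 2 sgRNAs. Genes were kept by filterByExpr with a minimum count of 10, libraries were scaled by TMM, and groups were compared with the quasi-likelihood F test of edgeR 4.0.16 (robust fit) in R 4.3.3. P-values were adjusted over all genes tested in a comparison by Benjamini-Hochberg, and genes below an adjusted p of 0.05 are called past the threshold. Each comparison of 2 groups used the libraries of those groups. The comparison of late unsorted cells with T0 took the reporter as a term, since each reporter had 1 T0 library. The difference between the Shank2 and Mef2d sorts was tested as a contrast of 4 groups in 1 fit. Log2 fold changes are the first group over the second and are given with their standard error (SE). A gene at 0 in every library of a group was given a lower bound from a floor of 3 counts over that group.

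Replicate numbers were taken to pair libraries within a comparison because, per the labels, high and low gates of a sort with the same number share the T number, as do 2% gates and unsorted cells of a line. Some replicates of a line share a T number, so it cannot tell their pairs apart. Mef2d 2% replicates 2, 3 and 4 are all at T16, as are Srrm4 replicates 1 and 2. The T numbers of the Mef2d 30% gates differ from those of the 2% gates and unsorted cells for some numbers, and these were not paired. The deviations of libraries from their group means were correlated across genes. Between gates of the same number r was -0.00658 to 0.0321 in the Shank2 sort, -0.00621 to 0.0308 in the Mef2d 2% sort, 0.0478 to 0.103 in the Mef2d 30% sort and 0.00205 to 0.0128 in the Srrm4 sort. Libraries of the high gate matched their own number best in 3 of 5, 2 of 4, 4 of 5 and 3 of 3 pairs. Against unsorted cells r was 0.0141 to 0.203 and 0.00696 to 0.133 for the Shank2 high and low gates (best in 3 and 2 of 5), -0.0197 to 0.147 and -0.0504 to 0.0795 for Mef2d (1 of 3 each) and 0.0184 to 0.0348 and 0.0213 to 0.0666 for Srrm4 (3 of 3 each). The pairing thus rests on the labels, since r was over 0.1 for every pair in none of the 10 comparisons. The replicate number as a block was run as an alternative. The labels do not say whether replicates are separate infections, so p-values measure the spread between these sorted cultures and no more. Across 74 pairs of replicates, counts differed by more than counting error (chi-square per degree of freedom 4.67 to 54.2), and 0 pairs were identical.

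Gene lists, 37 in all, were written before the data were examined, as were the comparisons, the tests, the alternatives named first below and the rule for named genes. By that rule, Srrm4, Srsf11 and Rnps1 are named in each comparison of high with low gates. The 10 genes with the smallest p in each direction follow, where all but at most 1 sgRNA moved with the gene, and then up to 4 members of each list past the threshold. For gates against unsorted cells, Srrm4 and the 3 smallest p in each direction are named, for the difference between reporters the 5 smallest, and for late cells against T0 the 10 smallest, each by the same conditions, with list members as above. Lists were tested with camera (limma 3.58.1, preset correlation 0.01, log2 CPM, the count relative to library size, with a prior count of 2), also with an estimated correlation, and with fry, which asks whether a list's genes move one way on balance and does not compare them with other genes. The 2-gene list of Srsf11 and Rnps1 was remembered from the study itself, so its counts are not independent evidence. Overlaps used one-sided Fisher's exact tests. Intervals over genes, unlike those of counts, take genes as independent and do not measure the spread between libraries.

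The test was tried on simulated data made from the deposited counts with known changes. In the Shank2 design, edgeR recovered 2 of 50 genes changed by 2 on the log2 scale, 15 of 46 changed by 3 and 38 of 45 changed by 4. In the Mef2d 2% design it recovered 4 of 49, 16 of 49 and 37 of 46, and in the Srrm4 design 2 of 50, 7 of 50 and 31 of 48. In the Mef2d 30% design 43 of 50 genes changed by 2 were recovered, and for late cells against T0 all 50 genes changed by 1. Its calls included unchanged genes: 7 (11.3% of calls) in the Shank2 design, 3 (5%) in the Mef2d 2%, 8 (5.16%) in the Mef2d 30% and 6 (13.0%) in the Srrm4 design, and 6 (2.91%) for late cells. Camera called the changed list in each of 5 designs and 0 of 20 random lists.

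Alternatives chosen then were scaling by total counts, DESeq2 1.42.0, no filter on low counts, a fit without robust estimation, sgRNA-level tests joined by robust rank aggregation (RRA), limma on the mean over sgRNAs of log2(CPM + 1), only sgRNAs with at least 30 counts at T0, the replicate block, all libraries of a reporter in 1 fit, and leaving out each library in turn. Alternatives added after seeing the data were leaving out the 2 libraries with over 50% of sgRNAs at 0, limma voom with library quality weights, leaving out the earliest unsorted libraries, and scaling libraries within each chromosome. Some genes that the rule takes are not reported here. The plasmid library was not compared with cells, and sgRNAs without a gene name were examined only as a share of counts and against sgRNAs of olfactory genes.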

Results

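Read counts of single guide RNAs (sgRNAs), each directing Cas9 to inactivate 1 gene, were obtained for 48 libraries of N2A cells, a mouse neuroblastoma line, and for 1 library of the plasmid pool. More counts of a gene's sgRNAs in one gate than in another report that cells without that gene were found there more often. The Shank2 line gave 5 libraries each from the 2% of cells with the highest EGFP:mCherry ratio (high gate), the 2% with the lowest (low gate) and unsorted cells. The Mef2d line gave 4 and 4 from the 2% gates, 5 and 5 from the 30% gates and 3 from unsorted cells. The Srrm4 line gave 3 each from both 2% gates and unsorted cells. Each line had 1 library from the start of the screen (T0), so T0 and the plasmid pool have no replicates.

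Depth differed strongly between kinds of library. The 2% gates held 824674 to 2993915 counts with 10.2% to 73.1% of sgRNAs at 0. By the cell numbers of the labels, 3.82 to 6.36 cells were sorted per sgRNA. How many of them reached each library was not measured. The 30% gates held 6472180 to 14197812 counts (1.31% to 19.6% at 0), unsorted cells 6641321 to 26063095 (0.448% to 4.31%) and T0 16066802 to 24925065 (0.0585% to 0.148%). The plasmid library held 35161922 counts with 0.0292% of sgRNAs at 0. The sparsest libraries were the Shank2 low gate replicate 3 (73.1% at 0) and the Mef2d 2% low gate replicate 4 (60.3%).

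Which gene losses move the Shank2 microexon reporter was asked by comparing its 2% gates (5 libraries each). sgRNAs against Rbfox2 and Srrm3 were higher in the high gate, and those against Rbm17 and Uros were lower. Rbfox2, a splicing factor that binds GCAUG motifs (chromosome 15, 77078990 to 77308434), took 753 ± 263 counts relative to library size (CPM) in the high gate and 26.1 ± 19.1 in the low gate (SD, n = 5), a log2 fold change of 4.84 ± 0.61 (SE, adjusted p = 0.0112). Srrm3, a paralog of Srrm4 that promotes microexon splicing (chromosome 5, 135806860 to 135874773), took 446 ± 127 against 19.3 ± 20.9 CPM (4.52 ± 0.62, adjusted p = 0.0248). Rbm17, a factor in 3′ splice site choice (chromosome 2, 11585439 to 11603199), took 7.94 ± 4.90 against 367 ± 123 CPM (-5.47 ± 0.63, adjusted p = 0.0112), and Uros, a heme synthesis enzyme (chromosome 7, 133686142 to 133710467), took 24.3 ± 7.22 against 240 ± 116 (-3.29 ± 0.41, adjusted p = 0.0112). All 4 sgRNAs of each of these genes moved with the gene.

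Of the 33 known regulators of microexons and neural splicing tested in the Shank2 sort, 2 rose, 0 fell and 31 did not pass, and 9 passed when adjusted over the list alone. Their median log2 fold change was 0.38 (camera adjusted p = 0.0599; adjusted p = 0.312 with an estimated correlation), and fry gave an adjusted p of 0.0403. Srrm4, the activator of neuronal microexons, stood at 4.16 ± 0.87 without passing (adjusted p = 0.235), as did Ep300, a histone acetyltransferase, at 4.19 ± 0.82 (0.177), the latter chosen after its value was seen. Of 12 factors of 3′ splice site recognition, 0 rose, 1 fell (Rbm17) and 4 passed adjusted over the list alone (median -0.41, camera adjusted p = 0.191). Rnps1 stood at 2.30 ± 0.74 (0.752) and Srsf11, an SR-related protein, at -0.28 ± 1.55 (1.00). Neither passed, and this pair was chosen by the study on these samples, so it is not independent evidence. None of the 37 lists passed camera. With replicates as a block it called 4 (microexon regulators, tri-snRNP, RNA exosome and proteasome, adjusted p = 0.0466 each), and fry also called nonsense-mediated decay (0.0403). The signs of median, mean and test differed for 3 of the lists.

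In the Shank2 sort, 2 genes were higher and 2 lower of 19016 tested with edgeR, and 919 had an unadjusted p under 0.05. With replicates as a block 0 genes passed (730 at an unadjusted p under 0.05; Rbfox2 0.220, Srrm3 0.118, Rbm17 0.135, Uros 0.220), and over all alternatives the adjusted p ranged from 2.44e-17 to 0.220 for Rbfox2, 1.06e-11 to 0.143 for Srrm3, 8.84e-27 to 0.135 for Rbm17 and 3.38e-13 to 0.220 for Uros. Other tools called 182 genes (DESeq2, 110 higher and 72 lower), 32 (RRA), 49 (limma on sgRNA means) and 44 (voom), and scaling by total counts gave 2 higher and 5 lower. Leaving out 1 library gave 0 genes without high gate replicates 3 or 5 or low gate replicate 2, and 1 without high gate replicate 1. It gave 2 without high gate replicate 2 or low gate replicates 4 or 5, and 47 (31 higher, 16 lower) without the sparse low gate replicate 3. Per the labels, this library is also the only one of its gate at T9 (others T15, T17, T22 and T24). Its sparsity and its T number cannot be told apart. Without that library Srrm4 passed at 3.84 (adjusted p = 0.000659, range over alternatives 1.46e-09 to 0.994), Hira at 3.37, U2surp at -4.58 and Srsf6 at -4.68, the latter 3 chosen after their values were seen. The microexon regulators then passed camera (4 higher, 2 lower, adjusted p = 0.00565; adjusted p = 0.124 with an estimated correlation). Genes on chromosome 15, which holds Rbfox2 and Ep300, shifted together (median 0.69 over 688 genes, other chromosomes -0.09 to 0.10), and with libraries scaled within each chromosome Rbfox2 stood at 4.20 (adjusted p = 0.0306).

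**Figure D1:**
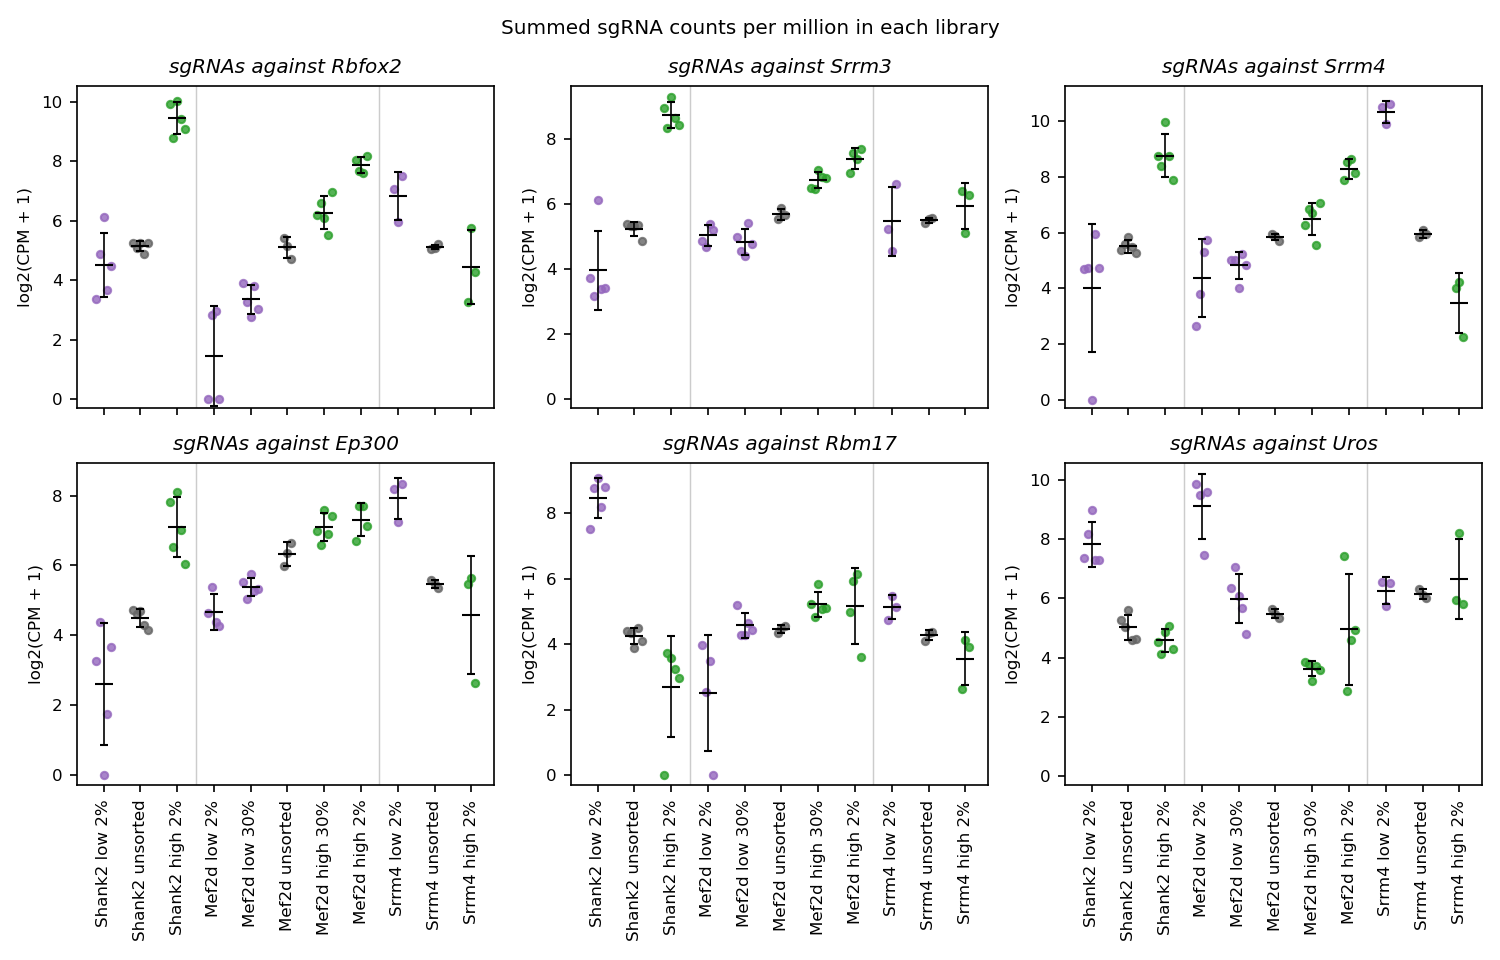
Log2(CPM + 1) of the summed sgRNA counts of Rbfox2, Srrm3, Srrm4, Ep300, Rbm17 and Uros (y axis) in 11 groups of libraries (x axis); dots are libraries, black lines means and bars SD. Rbfox2 took 753 ± 263 CPM in the Shank2 high gate against 26.1 ± 19.1 in the low gate, and Srrm4 took 12.01 ± 7.25 CPM in the high gate of its own sort against 1323 ± 339 in the low gate.

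The Mef2d microexon reporter put the same question to a different exon, first with 2% gates (4 libraries each). sgRNAs against 7 genes were higher in the high gate: Tnpo1, U2af1, Hira, Srrm3, Rbfox2, Srm and Ep300. Tnpo1, an importin for RNA-binding proteins, took 118 ± 37.3 CPM in the high gate (SD, n = 4) and 0 counts in all 4 low gate libraries, at least 254-fold higher against a floor of 3 counts over the group (adjusted p = 0.00353). U2af1, the U2AF subunit that reads the 3′ splice site, was at least 246-fold higher by the same floor (0.00495), with 1 sgRNA at 6.58 on the log2 scale and the other 3 at 0.49 to 0.91. Hira, a chaperone of histone H3.3, rose by 4.08 ± 0.45 (0.00495), Srrm3 by 2.41 ± 0.33, Rbfox2 by 6.18 ± 0.80 and Srm, which makes spermidine, by 2.81 ± 0.39 (0.0255 each), and Ep300 by 2.68 ± 0.39 (0.0415).

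By list, 7 of 37 passed camera in the Mef2d 2% sort, 6 of them upward. Of 25 tri-snRNP genes 0 passed alone, yet their median was 1.29 (camera adjusted p = 2.57e-07; adjusted p = 0.0393 with an estimated correlation; fry 0.00246). Of 13 factors of 3′ splice site recognition 1 rose (U2af1) and 1 passed adjusted over the list alone (median 1.25, 0.000422; adjusted p = 0.0943 with an estimated correlation). The filter on low counts left some list members untested. The library holds 31 tri-snRNP, 15 U2 snRNP, 29 Prp19 complex and 11 exon junction complex genes. The 8 U2 snRNP genes tested had 0 past the threshold (median 1.30, 0.00437; adjusted p = 0.375 with an estimated correlation), as did the 24 Prp19 complex genes tested (0.79, 0.0182; adjusted p = 0.163 with an estimated correlation) and the 9 exon junction complex genes tested (0.77, 0.0116; adjusted p = 0.375 with an estimated correlation). The 31 genes of cullin ligases and the COP9 signalosome also had 0 past it and a median of -0.71 (0.000986; adjusted p = 0.420 with an estimated correlation). Srsf11 (1.86 ± 0.56, adjusted p = 0.832) and Rnps1 (2.16 ± 0.37, 0.124) did not pass alone, both passed adjusted over their list, and the list had a median of 2.01 (0.000986; adjusted p = 0.0990 with an estimated correlation). The study chose that pair on these samples, so it is not independent evidence. Of the 33 microexon regulators 2 rose and 9 passed adjusted over the list alone (median 0.51, camera 0.0648; adjusted p = 0.241 with an estimated correlation; fry 0.000175), with Srrm4 at 3.57 ± 0.58 (0.103). Median, mean and test differed in sign for 8 lists.

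In the Mef2d 2% sort, 7 genes were higher and 0 lower of 19177 tested with edgeR, with 914 at an unadjusted p under 0.05. DESeq2 called 135 (54 higher, 81 lower), RRA 18, limma on sgRNA means 32 (28 higher, 4 lower) and voom 0. With replicates as a block 0 passed; the 7 genes then had adjusted p from 0.426 to 0.763, and for Rbfox2 the range over alternatives was 7.42e-11 to 0.763. Leaving out 1 library gave 2 genes without high gate replicate 3 or low gate replicate 2, 3 without high gate replicates 2 or 4 or low gate replicate 3, and 15 without the sparse low gate replicate 4. Chromosomes shifted here too, with medians of -0.47 on chromosome 10, -0.40 on 16, which holds Hira, 0.31 on 13, which holds Tnpo1, and 0.36 on 15, which holds Rbfox2 and Ep300. With libraries scaled within each chromosome Ep300 stood at 2.34 (adjusted p = 0.132, over alternatives 4.92e-10 to 0.477), and the other 6 genes passed.

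The 30% gates of the Mef2d line, which were deeper, asked which losses move this reporter in a wider slice of cells (5 libraries each). The labels give no number of sorted cells for these gates. Rbfox2 took 80.5 ± 29.3 CPM in the high gate and 9.77 ± 3.62 in the low gate (SD, n = 5), a log2 fold change of 3.03 ± 0.31 (adjusted p = 7.24e-06). Srrm3 rose by 1.91 ± 0.22 (6.22e-05) and Srrm4 by 1.71 ± 0.26 (0.00170). Higher as well were Ep300 (1.75 ± 0.21), the LIM-domain cofactor Ldb1 (1.67 ± 0.20) and Hira (2.02 ± 0.25), each at 6.81e-05, and the kinase Tlk2 (1.56 ± 0.22) and the neuronal RNA-binding protein Elavl2 (1.43 ± 0.20), each at 0.000523. Uros fell by 2.63 on the log2 scale (SE 0.33, 7.68e-05, 3 of 4 sgRNAs), and Mbnl1, a splicing factor that binds YGCY motifs, fell by 1.36 (SE 0.23, 0.00393).

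Of 33 microexon regulators, 6 rose, 1 fell (Mbnl1), 26 did not pass, and 11 passed adjusted over the list alone (median 0.12, camera adjusted p = 0.00361; adjusted p = 0.101 with an estimated correlation; fry 0.00241). Those that rose were Rbfox2, Srrm3, Srrm4, Elavl2, Celf1 (3.91 ± 0.55) and Elavl4 (1.03 ± 0.18), the last pair named after their values were seen. Of 14 factors of 3′ splice site recognition 1 rose, Cherp (1.74 ± 0.32, 0.0115), and 2 passed adjusted over the list alone (median 0.47, 0.00908; adjusted p = 0.201 with an estimated correlation). Among 34 cullin ligase and COP9 genes 1 rose and 2 fell, Cops8 (-1.75 ± 0.29, 0.00393) and Cops3 (-1.54 ± 0.32, 0.0387), both COP9 subunits, and 11 passed adjusted over the list alone (median -0.20, 0.00908; adjusted p = 0.148 with an estimated correlation). Srsf11 rose by 1.50 ± 0.27 (0.0115) and Rnps1 stood at 0.44 ± 0.23 (0.644). That pair, not independent evidence since the study chose it on these samples, had 1 member past the threshold, also adjusted over the list alone (median 0.97, 0.00908; adjusted p = 0.148 with an estimated correlation; fry 0.0361). The tri-snRNP (31 genes, median 0.29, 0.0187; adjusted p = 0.688 with an estimated correlation) and nonsense-mediated decay (15 genes, 0.11, 0.00908; adjusted p = 0.148 with an estimated correlation) passed upward with 0 genes past the threshold. The RNA exosome (17 genes, -0.36, 0.00908; adjusted p = 0.560 with an estimated correlation) and the proteasome (33 genes, -0.32, 0.0187; adjusted p = 0.560 with an estimated correlation) passed downward, also with 0. Median, mean and test differed in sign for 8 lists, none past the threshold.

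Further genes higher in the Mef2d 30% high gate were the deubiquitinase Otud5 (1.59 ± 0.27), the U1 protein Snrpa (1.68 ± 0.34), the SMAD cofactor Smad4 (1.02 ± 0.19), the translation factor Eif4g2 (1.02 ± 0.20) and the chromatin protein Phf21a (1.02 ± 0.21). Lower were the Mediator subunit Med16 (-1.35 ± 0.23), the PTB-binding protein Raver1 (-1.14 ± 0.22), Bend3 (-1.44 ± 0.29), the transcription factor Creb1 (-1.23 ± 0.26), the phosphate exporter Xpr1 (-0.93 ± 0.20) and BC021785 (-1.05 ± 0.21). With replicates as a block Eif4g2 (adjusted p = 0.0696), Snrpa (0.0868), Raver1 (0.0530), Bend3 (0.167), Cops3 (0.0999), Xpr1 (0.0634) and Creb1 (0.0634) no longer passed. Over alternatives the adjusted p of these ranged from 1.52e-05 to 0.199 for Eif4g2, 8.12e-05 to 0.473 for Snrpa, 0.000607 to 0.214 for Bend3, 0.000190 to 0.309 for Xpr1 and 0.000426 to 0.276 for Creb1. For Raver1 it ranged from 4.46e-05 to 1.00 and for Cops3 from 0.000437 to 1.00.

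In the Mef2d 30% sort, 29 genes were higher and 11 lower of 19601 tested with edgeR, with 28 (21 higher, 7 lower, 22 shared) under the replicate block. DESeq2 called 195 (99 higher, 96 lower), RRA 24, limma on sgRNA means 23, voom 157 (80 higher, 77 lower), and 1 fit of all Mef2d libraries 6. Leaving out 1 library gave 21 genes without high gate replicate 5, 17 without low gate replicate 2, 26 without low gate replicate 3 and 22 without low gate replicate 5. Rbfox2, Srrm3, Srrm4, Ep300, Ldb1, Hira, Tlk2, Elavl2, Uros, Cops8, Mbnl1 and Med16 passed without each of the 10 libraries, Creb1, Xpr1 and Snrpa without 2 of them. Medians were -0.26 on chromosome 10, which holds Med16 and Bend3, -0.22 on 16, which holds Hira, 0.14 on 13 and 0.20 on 15, which holds Rbfox2 and Ep300. With libraries scaled within each chromosome 25 were higher and 6 lower, 30 of them shared; Raver1 (-1.02, 0.0618), Bend3 (-1.18, 0.145), Xpr1 (-0.84, 0.0897), Creb1 (-1.13, 0.0897) and Phf21a (0.93, 0.0655; 0.000166 to 1.00 over alternatives) did not pass.

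**Figure D2:**
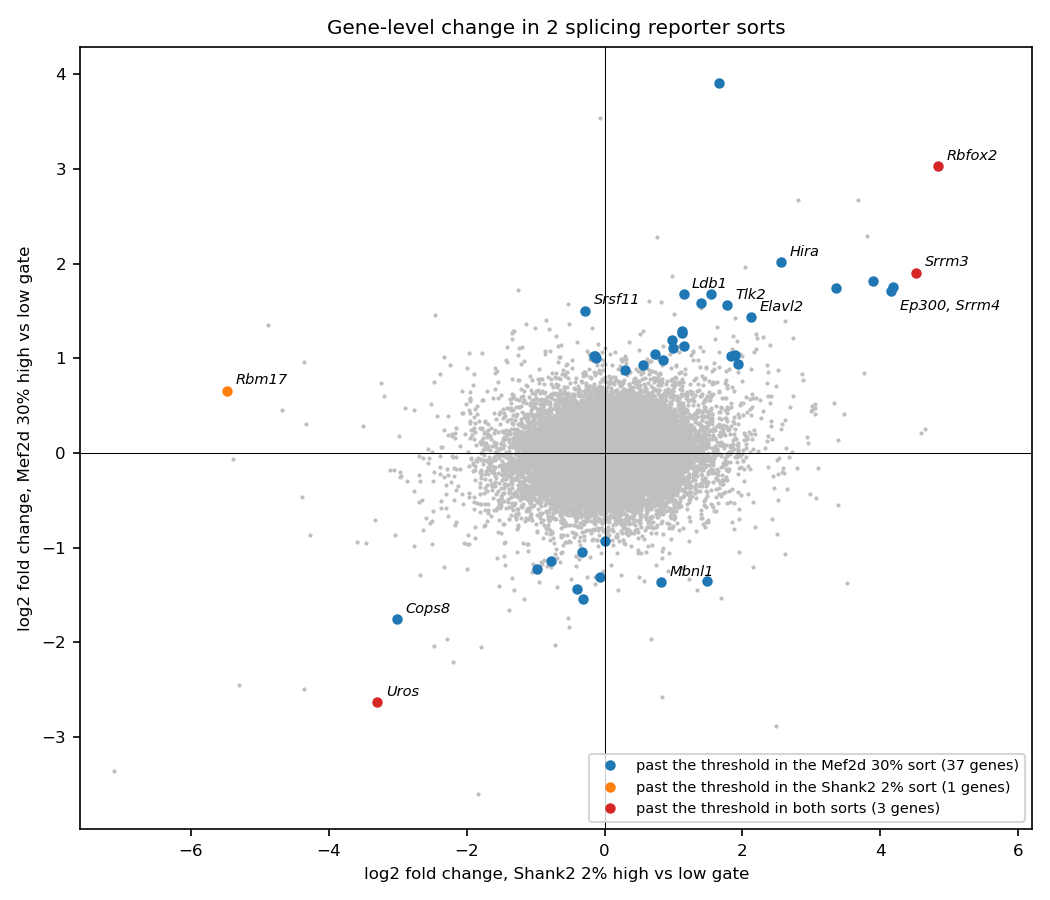
Log2 fold change, high over low gate, of each gene in the Shank2 2% sort (x axis) and the Mef2d 30% sort (y axis); blue points passed in Mef2d (37), the orange point in Shank2 (Rbm17), red points in both (Rbfox2, Srrm3, Uros), grey points in neither. Rbfox2 lies at 4.84 and 3.03, Srrm3 at 4.52 and 1.91 and Uros at -3.29 and -2.63.

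**Figure D3:**
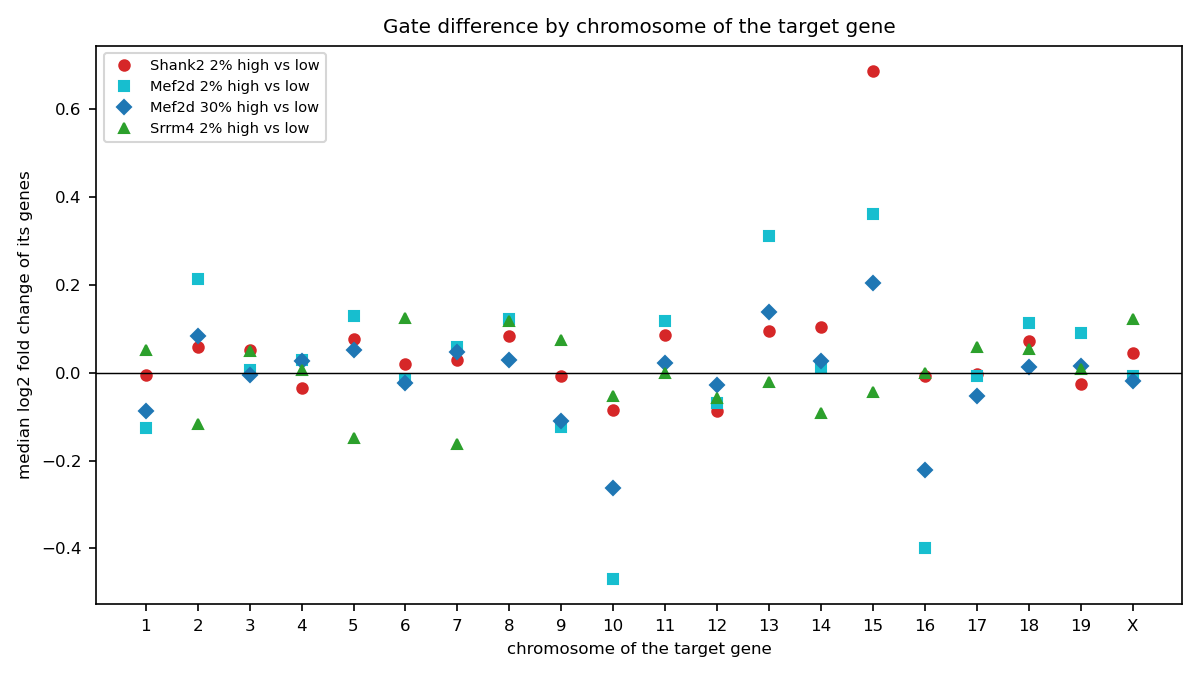
Median log2 fold change, high over low gate, of the genes on each chromosome (x axis, 1 to 19 and X) in the 4 sorts (y axis and color). Chromosome 15 stands at 0.69 in the Shank2 sort, where the other chromosomes lie from -0.09 to 0.10, and chromosome 10 at -0.47 in the Mef2d 2% sort.

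The third line reads the level of the Srrm4 protein itself, and its gates asked which losses change that level (3 libraries each). sgRNAs against Srrm4 (chromosome 5, 116439268 to 116592562) took 12.01 ± 7.25 CPM in the high EGFP gate and 1323 ± 339 in the low gate (SD, n = 3). The log2 fold change was -6.75 ± 0.64 (adjusted p = 0.000397), 4 of 4 sgRNAs went the same way, and Srrm4 was the 1 gene past the threshold of 19175 tested with edgeR. Srsf11 stood at -1.82 ± 1.37 and Rnps1 at -0.73 ± 0.48 (adjusted p = 0.996 each). Of the microexon regulators 1 fell (Srrm4) and 32 did not pass, 1 passed adjusted over the list alone (median -0.19, camera 0.243), and none of the 37 lists passed camera. Fry called 1, the 24 SR proteins, of which 0 passed and 3 passed adjusted over the list alone (median -0.21, fry 0.0227, camera 0.243). Signs of median, mean and test differed for 10 lists.

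For Srrm4 in its own sort the adjusted p was 0.0763 with replicates as a block, which gave 0 genes, 0.0588 under RRA, 0.0626 under voom and 0.0655 without high gate replicate 1 (1.77e-57 to 0.0763 over alternatives). In the last pair of these 1 other gene passed, Matn2 under voom and U2af1 without that library, both named after their values were seen. A total of 907 genes had an unadjusted p under 0.05, DESeq2 called 114 (45 higher, 69 lower), RRA 0 and limma on sgRNA means 6. Without high gate replicate 2 edgeR called 2 higher and 14 lower, and without low gate replicate 1 it called 1 and 1. The median of chromosome 5 genes in this sort was -0.15 and that of chromosome 7 was -0.16, and Srrm4 stood at -6.63 with libraries scaled within each chromosome.

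Each gate was next set against unsorted cells of its line, to see which gate held the change. In the Shank2 high gate, sgRNAs against 122 genes were higher than in unsorted cells and 3 lower (19513 tested, 5 libraries each). Of these 125 genes, 93 had all but at most 1 sgRNA moving with the gene. The rest, Rbl1 among them with 2 of 4, had less sgRNA support. Rbfox2 rose by 4.46 ± 0.30 and Srrm3 by 3.62 ± 0.26 (adjusted p = 6.26e-06 each), Srrm4 by 3.49 ± 0.36 (0.000393) and the histone demethylase Kdm3a by 2.08 ± 0.20 (0.000246). Microexon regulators made up 6 of the higher genes against 0.206 by chance (Celf1, Elavl2, Elavl4, Rbfox2, Srrm3, Srrm4; one-sided Fisher's exact adjusted p = 1.88e-06 over 37 lists), and tumour suppressors 3 (Ambra1, Cdkn1b, Rbl1; 0.0342). Lower were L3hypdh (-1.21 ± 0.23, 0.0262), the adaptor Skap2 (-1.77 ± 0.35, 0.0345) and the helicase Ddx24, with 1 count in 5 high gate libraries against 1061 in unsorted cells (106-fold, counting interval 19.003 to 4195, 0.0346). Of the higher genes 43 lay on chromosome 15, where 4.40 were expected and the median of all 704 genes was 0.527.

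For the Shank2 high gate against unsorted cells, the replicate block gave 70 higher and 0 lower genes, 67 of them shared, and L3hypdh (0.115), Skap2 (0.126) and Ddx24 (0.1999) no longer passed; over alternatives their highest adjusted p values were 0.797, 0.797 and 0.1999. Scaling within each chromosome gave 65 higher and 0 lower, DESeq2 683 and 234, RRA 51, voom 304 and 130, and limma on sgRNA means 39 and 6181. The limma and voom medians of all genes lay at -0.82 and -0.17, where edgeR had 0.0027, and over all gates against unsorted cells limma medians lay from -1.02 to -0.59. Leaving out 1 library gave 402 genes (328 higher, 74 lower) without high gate replicate 3, 68 without high gate replicate 4, and 41, 35, 45, 36 and 41 without unsorted replicates 1 to 5. High gate replicate 3 is the only library of its gate at T9.

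In the Shank2 low gate against unsorted cells 1 gene was higher, Rbm17 (4.35 ± 0.32, adjusted p = 0.000528), and 0 were lower of 19515, with 816 at an unadjusted p under 0.05. Srrm4 stood at -0.67 ± 0.81 (1.00). Under the replicate block Rbm17 had an adjusted p of 0.0947 (2.65e-53 to 0.0947 over alternatives) and 0 genes passed. DESeq2 called 203, RRA 15, voom 138, limma on sgRNA means 8 higher and 4798 lower, total-count scaling 2, and edgeR 43 (41 higher, 2 lower) without the sparse low gate replicate 3.

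In the Mef2d 2% high gate (4 libraries against 3 unsorted) 4 genes were higher and 0 lower of 19462, with 602 at an unadjusted p under 0.05. They were the RNA-binding protein Celf1 (3.92 ± 0.35, adjusted p = 0.00362), Rbfox2 (2.84 ± 0.29, 0.00760), Srrm4 (2.53 ± 0.29, 0.0138) and Gpatch8 (2.06 ± 0.25, 0.0180), the last named after its value was seen. The replicate block gave 10, DESeq2 70, RRA 23 and voom 25, and 0 genes passed without high gate replicate 2 or unsorted replicates 2 or 3. In the Mef2d 2% low gate the RNA-binding protein Qk (3.24 ± 0.29) and the ubiquitin-conjugating enzyme Ube2g1 (3.41 ± 0.33) were higher (0.0448 each) and 0 lower of 19333, with 602 at an unadjusted p under 0.05, and Srrm4 stood at -1.04 ± 0.69 (1.00). There DESeq2 called 204, RRA 11, voom 54 and limma on sgRNA means 0. A count of 0 followed without low gate replicates 1 or 2 or any of the 3 unsorted libraries, and 1 without low gate replicate 3.

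In the Srrm4 high gate 0 genes passed against unsorted cells of 19475 tested with edgeR (3 libraries each), with 1101 at an unadjusted p under 0.05. DESeq2 called 371, RRA 5, voom 5 and limma on sgRNA means 0, and Srrm4 stood at -2.30 ± 0.53 (adjusted p = 0.874). In the Srrm4 low gate Srrm4 rose by 4.47 ± 0.30 (0.00139) and Ep300 by 2.61 ± 0.29 (0.0458). The remaining 2 of 4 higher genes, named after their values were seen, were U2af1 (5.27 ± 0.33, 0.00136, 1 of 4 sgRNAs) and Fam133b (2.33 ± 0.24, 0.0354, 2 of 4 sgRNAs), and 0 were lower of 19486, with 1480 at an unadjusted p under 0.05. The replicate block gave 11, DESeq2 568, voom 101 and limma on sgRNA means 1. Without 1 library edgeR gave 2 (low gate replicate 1), 19 (low gate replicate 2), 2, 0 and 1 (unsorted replicates 1 to 3).

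Whether a gene acted differently on the 2 reporters was tested as the difference of their 2% high to low changes, Shank2 minus Mef2d. Rbm17 differed by -7.97 ± 1.04 (adjusted p = 0.00222), standing at 2.49 ± 1.14 in the Mef2d sort, where it did not pass, and at -5.47 in the Shank2 sort. U2surp, a U2 snRNP-associated protein, differed by -6.10 ± 1.01 (0.0426), from -4.36 ± 0.67 in Shank2 and 1.73 ± 0.95 in Mef2d, with neither past the threshold alone. These 2 of 19513 genes passed with edgeR, both lower in Shank2. With replicates as a block Rbm17 kept a difference of -8.47 (0.0158; 1.91e-16 to 0.0469 over alternatives) and U2surp had an adjusted p of 1.00 (2.86e-08 to 1.00). DESeq2 called 22 (16 higher, 6 lower), RRA 4, limma on sgRNA means 6 and voom 5. Leaving out 1 library gave 5 genes without the sparse Shank2 low gate replicate 3, 3 without Shank2 low gate replicate 1, 2 without the sparse Mef2d low gate replicate 4 and 1 without any other of the 18 libraries.

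Overlap between sorts was tested for genes past the threshold in the same direction. Rbfox2 and Srrm3 were higher in both the Shank2 and Mef2d 2% high gates (expected 0.000741, one-sided Fisher's exact adjusted p = 7.06e-07) and in the Mef2d 30% high gate (8.98e-06), and Uros was lower in the Shank2 and Mef2d 30% high gates (0.00347). Both Mef2d sorts shared Ep300, Hira, Rbfox2 and Srrm3 (expected 0.0106, adjusted p = 1.77e-09). No sort shared a gene in the same direction with the Srrm4 sort, where 1 gene passed, Srrm4 itself. Srrm4 passed in the Mef2d 30% sort as well, but in the opposite direction, higher there and lower in the Srrm4 high gate. Overlap in opposite directions was not tested. The Mef2d sorts come from 1 line with 1 T0 library and may share cultures. Their overlap is thus not independent evidence. Across genes, which are not independent replicates, log2 fold changes of Shank2 and Mef2d 2% correlated with Pearson's r = 0.105 (Spearman's rho = 0.0608), Shank2 and Mef2d 30% with 0.134 (0.0858) and both Mef2d sorts with 0.341 (0.257). With the Srrm4 sort Pearson's r was -0.0224, -0.0344 and -0.0334.

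Which genes N2A cells need to grow was asked by comparing late unsorted cells (11 libraries) with T0 (3 libraries, 1 per line). sgRNAs against genes of the ribosome, spliceosome, proteasome and replication machinery fell. Log2 fold changes were -5.27 ± 0.37 for Rps6, a small ribosomal subunit protein, and -3.11 ± 0.22 for Kars, the lysyl-tRNA synthetase (adjusted p = 1.59e-09 each), and -7.26 ± 0.56 for Rps13 and -4.98 ± 0.38 for Hars (5.83e-09 each). Nup160 of the nuclear pore stood at -5.04, the export receptor Xpo1 at -4.58, Paics of purine synthesis at -4.65, Rabggtb at -4.58, Umps of pyrimidine synthesis at -3.79 and Xab2 at -4.82. The genes with the smallest p among those that rose did so by less: Lmo7 0.62 ± 0.10 (3.90e-05), the stress kinase Map2k4 0.61 ± 0.11 (0.000169), Cacul1 0.66, the olfactory receptor Olfr902 0.55, the corepressor Ctbp2 0.64, Gskip 0.67, Map3k13 0.59, Pmm2 0.52, Ormdl1 0.62 and Scgb2b15 0.60. Of 1079 olfactory genes, listed as genes these cells should not use, 83 were higher, beside 1305 of all 19663 genes. A rise alone therefore does not show that a gene restrains growth.

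Of the 37 lists 30 passed camera, each downward, and 23 also with an estimated correlation. All 32 small ribosomal subunit genes fell (median -3.90), as did 44 of 45 large subunit genes (-4.33, 1.71e-34), 33 of 33 proteasome genes (-2.83, Psma3 -4.29), 39 of 39 DNA replication genes (-2.54, Pcna -5.07) and 27 of 30 translation initiation genes (-2.67, Eif6 -4.78). Among splicing lists 30 of 31 tri-snRNP genes fell (-1.93, 6.28e-23), 22 of 24 Sm and assembly genes (Snrpf -6.62), 14 of 15 U2 snRNP genes (Phf5a -6.30, Sf3b5 -4.61), 24 of 29 Prp19 complex genes (Prpf19 -4.76), 11 of 14 factors of 3′ splice site recognition, 11 of 13 minor spliceosome genes (Snrnp35 -3.33), 6 of 11 exon junction genes (Eif4a3 -4.38) and 5 of 11 U1 genes (Snrnp70 -2.73). SR proteins had 13 lower and 1 higher of 27 (Srsf1 -5.57, Srsf3 -4.11), and hnRNP proteins 17 lower and 3 higher of 32 (Tardbp -4.01). In RNA turnover and export 15 of 17 nonsense-mediated decay (Upf1 -2.56), 15 of 18 exosome (Exosc2 -2.42), 16 of 20 cleavage and polyadenylation (Cpsf3 -4.59) and 15 of 23 export genes (Ncbp2 -6.42) fell. In transcription 25 of 34 elongation (Cdk7 -3.48), 22 of 31 Mediator (Med11 -1.75) and 10 of 15 Integrator genes (Ints9 -5.70) fell, as did 26 of 35 cullin and COP9 genes (Skp1a -3.20).

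The 7 late calls lost with an estimated correlation were m6A writers and readers (8 of 15 fell, Mettl16 -3.15; adjusted p = 0.0792 with an estimated correlation), SAGA and NuA4 (18 of 30, Trrap -3.00; 0.0556), COMPASS (12 lower and 3 higher of 20, Wdr82 -4.42; 0.0878), SWI/SNF (9 and 1 of 25, Smarce1 -3.13; 0.103), REST and SIN3 (8 and 1 of 20, Sin3a -2.07; 0.136), mTORC1 (15 and 1 of 31, Mtor -1.47; 0.117) and complex I (32 of 36, Ndufab1 -1.99; 0.0614). Counts adjusted over the list alone were close to these, at 31 for the tri-snRNP, 44 for the large ribosomal subunit and 14 for the U2 snRNP.

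The known microexon regulators did not pass late (3 higher, 2 lower, 5 adjusted over the list alone, camera adjusted p = 0.477), with a median of 0.08 and a mean of -0.07. Ptbp1, a repressor of neuronal exons, fell by 2.63 (SE 0.50, 0.00115) and Khdrbs1 stood at -0.88 ± 0.21, also lower, and Celf1 (0.49 ± 0.15) and Rbfox1 (0.38 ± 0.12) rose; with libraries scaled within each chromosome Rbfox1, on chromosome 16 (median 0.21), stood at 0.20 (adjusted p = 0.214, over alternatives 0.00752 to 0.784). Srsf11 fell by 0.81 (SE 0.28, 0.0429), and its pair with Rnps1, which is not independent evidence, gave a camera adjusted p of 0.397. Tumour suppressors split into 7 higher and 6 lower of 39 (15 adjusted over the list alone, 0.345, median 0.12, mean -0.03), with Rb1 (0.72 ± 0.15), the cyclin-dependent kinase inhibitors Cdkn1b (0.66 ± 0.14) and Cdkn2a (0.49 ± 0.11) higher and Fbxw7 lower (-1.01 ± 0.20). Among neuroblastoma and neuronal transcription factors 2 rose and 5 fell of 33 (0.705), with Myc at -3.78 ± 0.43 (2.34e-07), its partner Max at -1.76 ± 0.25 and Hand2 at -1.06. SR protein kinases (1 higher, 2 lower of 10, 0.924, median 0.03, mean -0.13) and Polycomb (3 higher, 2 lower of 26, 0.999) did not pass either. Olfactory and vomeronasal receptors, listed as genes these cells should not use, had 98 higher and 113 lower of 1387 (0.0746, median 0.08, mean -0.01), with Vmn2r44 at -3.57 and Vmn1r128 at -3.67 among the lower.

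Late against T0, 1305 genes were higher and 3052 lower of 19663 tested with edgeR with the line as a term. Scaling by total counts gave 2440 higher and 2870 lower, so the share of higher genes depends on the scaling, and RRA gave 9 and 1618. The higher genes numbered 415, 796 and 402 without the T0 library of the Shank2, Mef2d and Srrm4 line (2551, 2940 and 2668 lower), since each line has 1.

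**Figure D4:**
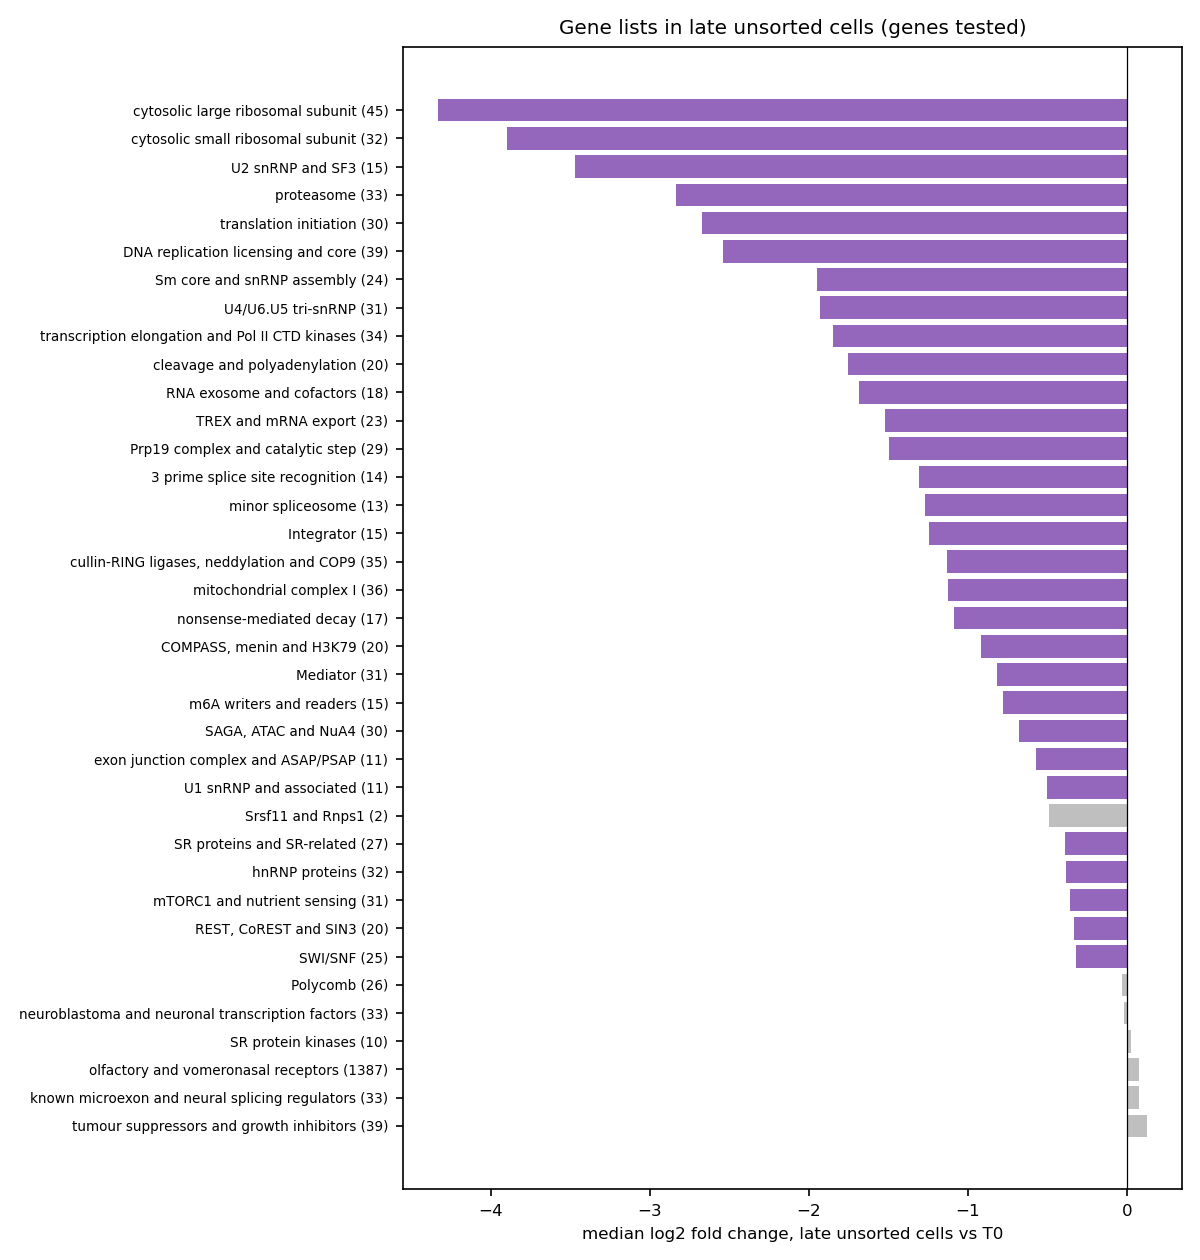
Median log2 fold change, late unsorted cells over T0, of each of the 37 gene lists (bars from 0; number of genes tested in brackets); purple bars are the 30 lists past camera's adjusted threshold, grey bars the other 7. The large ribosomal subunit stands lowest at -4.33, and the microexon regulators stand at 0.08.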

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

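The tests chosen only after the result was seen were the mean of Alas1 and Alad, the value of Uros in the Mef2d 2% sort, the 3 tests on chromosome 15, the receptor families and the alternatives that leave out sparse libraries, use voom or scale within chromosomes. Of 132 groups of 4 or 5 libraries examined for a library far from the rest, 11 held one, where chance flags about 1 in 20 groups, or 6.6. The Shank2 low gate replicate 3, the sparsest library, stood apart in 3 of them. Its share of counts from sgRNAs with no gene name was 1.66% (other replicates 1.90% to 1.92%), its log2(CPM + 1) of Srrm4 was 0 (4.70 to 5.93) and of Srrm3 6.11 (3.16 to 3.70). It is also the only library of its gate at T9. The T9 unsorted library of the Shank2 line likewise had the lowest such share of its group (1.78%, others 1.92% to 1.98%). The Mef2d 2% low gate replicate 4, also sparse, stood apart for Ube2g1 at 7.92 (8.78 to 8.90) and for U2surp at 0 (3.87 to 4.59). Log2(CPM + 1) also stood apart for Rbm17 in the Shank2 high gate replicate 1 at 0 (2.98 to 3.73) and Ddx24 in the Shank2 high gate replicate 3 at 0.566 (others 0), the latter from 1 count. The same holds for Srrm3 in Shank2 unsorted replicate 5 at 4.84 (5.30 to 5.36), Rnps1 in the Mef2d 30% low gate replicate 3 at 4.95 (5.63 to 5.90), Eif4g2 in replicate 5 of that gate at 4.97 (5.53 to 5.58) and Smad4 in the Mef2d 30% high gate replicate 5 at 7.03 (6.43 to 6.55).

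The 2 genes whose high to low change differed between reporters by a test of the difference were Rbm17 (-7.97, Shank2 minus Mef2d) and U2surp (-6.10). The sgRNAs with no gene name, outside every comparison, took a larger share in late unsorted cells than at T0: a mean of 1.92% against 1.37% in the Shank2 line, 1.78% against 1.34% in the Mef2d line and 1.76% against 1.40% in the Srrm4 line, with 1.25% in the plasmid pool.

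The first pattern weighed is the lower count of Uros sgRNAs in the high ratio gates of both splicing reporters. Loss of heme itself is argued against by Alas1 and Alad, which act early in the pathway, with a mean of -0.00280 ± 0.14 (SE) in the Mef2d 30% sort. A change in EGFP or cell state that any sort would read is argued against by Uros in the EGFP-only Srrm4 sort, at 0.78 ± 0.62, and chance sampling of few cells by the Mef2d 2% sort, where Uros did not pass (adjusted p = 0.678) but stood at -3.48 ± 0.86. That Mef2d 2% sort comes from the line of the Mef2d 30% sort and may share its cultures. Porphyrins that build up after loss of a late enzyme and add red signal may account for it, though this rests on the Mef2d 30% sort. There Ppox and Fech, which follow Uros in the pathway, had a mean of -1.10 ± 0.26, and neither passed alone (edgeR adjusted p = 0.327 each). Urod (-3.36 ± 0.77, adjusted p = 0.0706) and Cpox (-1.55 ± 0.36, 0.0785) lay on the same side without passing. Ppox and Fech stood at 0.25 ± 0.69 and 0.19 ± 1.12 in the Shank2 sort and at -0.43 ± 0.41 and -0.54 ± 1.18 in the Mef2d 2% sort, the red signal was not measured in these data, no effect of Uros on splicing was tested, and this stays a hypothesis.

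The second pattern is the shift of chromosome 15 genes upward in the Shank2 high gate, with 43 of the 122 higher genes there. A depth gap between gates and unsorted cells is argued against by the low gate, where the median of chromosome 15 genes was -0.187. Separate action of each gene is argued against by the chromosome 15 genes not past the threshold, whose median was 0.501, and loss of the chromosome end beyond a break is argued against by 304 genes before Rbfox2 at 0.487 and 399 beyond it at 0.571, a difference of -0.0836 (95% resampling interval -0.148 to -0.00706). Cells in the high gate that lost or gained the whole chromosome were not tested. Values of chromosome 15 genes in this sort, Rbfox2 and Ep300 among them, therefore carry a shift of about this size, which is far below the 4.46 of Rbfox2.

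The third pattern is the fall of some receptor genes that N2A cells should not use, 113 of 1387 and mostly vomeronasal, while 98 rose, 83 of them olfactory. Gain of a segment confined to receptor genes was not tested, since only the nearest 3 genes of other families on each side were read. Gain of a segment that reaches such neighbours is argued against by 197 genes of other families next to these 113, whose median was 0.0740 (95% resampling interval 0.0501 to 0.117; all other genes 0.0397). Breaks at several near-identical gene copies may account for it, since 23.1% of vomeronasal genes fell (71 of 308) against 3.89% of olfactory genes (42 of 1079; Fisher's exact p = 1.70e-22). A growth cost of any DNA break could add to it, as sgRNAs with no gene name rose over those of olfactory genes in each of 11 unsorted libraries, by at least 0.119 on the log2 scale, and the 2 are not exclusive. A need of these cells for the receptors was not tested.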

How the results depend on the processing

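Tests chosen only after the data were seen were those without the sparse libraries, without the earliest unsorted libraries, with voom and with scaling within each chromosome. Of 5223 values of named genes under alternatives, 4854 kept their direction and side of the threshold, 339 no longer passed, 25 newly passed and 5 reversed. Most of these values belong to late against T0, so the totals say little about the sorts. Under the replicate block 4 named genes no longer passed and 3 kept their side in the Shank2 sort. The same counts were 7 and 3 in the Mef2d 2% sort and 7 and 21 in the Mef2d 30% sort. The reversed values belong to genes not past the threshold as reported. These were Srsf11 in the Shank2 sort, past it under no alternative (0.402 under voom, and -0.80 to 0.245 without 1 library, with 0.0332 and 0.0488 also above 0) and Srrm4 in the Shank2 low gate against unsorted cells (0.38 under RRA), which passed only with limma on sgRNA means (-1.68, adjusted p = 0.0331; 0.0331 to 1.00 over the alternatives). For counts of genes, results are given in the order Shank2, Mef2d 2%, Mef2d 30% and Srrm4 high against low (4, 7, 40 and 1 as reported), Shank2 high and low against unsorted (125 and 1), Mef2d high and low (4 and 2), Srrm4 high and low (0 and 4), the reporter difference (2) and late against T0 (4357), leaving out results within 1.5 times the reported count. DESeq2 gave 182, 135, 195, 114, 917, 203, 70, 204, 371, 568 and 22. On simulated data a larger share of its calls than of edgeR's was false, and part of the rise may follow from that. RRA gave 32, 18, 24, 0, 51, 15, 23, 11, 5, 4 (the reporter difference) and 1627 (late). Limma on sgRNA means gave 49, 32, 23, 6, 6220, 4806, 0 (Mef2d low), 1 (Srrm4 low) and 6 (the reporter difference). Its median over all genes lay at 0.20 in the Shank2 sort, 0.35 in the Mef2d 2% sort, -0.14 in the Srrm4 sort and -0.16 for the reporter difference. Voom gave 44, 0 (Mef2d 2%), 157, 434, 138, 25, 54, 5 (Srrm4 high), 101 and 5 (the reporter difference). The replicate block gave 0 in the 3 sorts with 2% gates, 70, 0 (Shank2 low), 10 (Mef2d high), 11 (Srrm4 low) and 1 (the reporter difference), with medians over all genes at 0.15 in the Shank2 sort and -0.14 and -0.29 in its high and low gates against unsorted cells. Fitting all libraries of a line together gave 87, 248, 6 and 5. Total counts gave 7 in the Shank2 sort and 2 in the Shank2 low gate, sgRNAs with at least 30 counts at T0 gave 2 in that gate, no filter on low counts gave 2 in the Srrm4 sort, and a fit without robust estimation gave 2 in the Srrm4 sort and 0 in the Mef2d low gate. Leaving out the sparse libraries gave 47, 15, 43 (Shank2 low) and 8 (the reporter difference), and scaling within each chromosome gave 65 in the Shank2 high gate. Genes past the threshold in the same direction in at least 2 sorts numbered 5 as reported and became 14 at an adjusted p under 0.2, 14 under RRA and 12 without the sparse libraries. Gene lists past the threshold numbered 4 with the replicate block and 2 without the sparse library in the Shank2 sort (0 as reported), and with an estimated correlation 1 in the Mef2d 2% sort (7) and 0 in the Mef2d 30% sort (8). Without 1 library the counts ranged from 0 to 47 (Shank2), 2 to 15 (Mef2d 2%), 17 to 52 (Mef2d 30%), 1 to 16 (Srrm4), 35 to 402 and 1 to 43 (Shank2 high and low), 0 to 5 and 0 to 2 (Mef2d high and low), 0 to 0 and 0 to 19 (Srrm4 high and low), 1 to 5 (the reporter difference) and 2966 to 4584 (late). Except where stated, the cause was not tested. On simulated data edgeR recovered 2 of 50 genes changed by 2 on the log2 scale in the Shank2 design. In the Mef2d 30% design it recovered 43 of 50, so most changes of this size in the Shank2 gates may have been missed. These designs differ in depth and also in the spread between libraries (biological coefficient of variation 0.746 and 0.336). The part of depth alone was not tested. Apart from the set changes, simulated libraries of a design shared 1 mean profile and 1 dispersion, without a sparse library or shifts of chromosomes.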

Other observations

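None of the tests of the gene paragraphs or of chromosome 5 was chosen only after its result was seen; the tests off chromosome 15, in the Shank2 low gate, without sparse libraries, of chromosome shares and of the reporter difference by swapped pairs were. Of the COP9 signalosome, 9 subunits were tested in the Mef2d 30% sort, each with a negative edgeR log2 fold change. Beside those past the threshold Cops6 stood at -2.58 ± 0.70 (adjusted p = 0.188), Cops4 at -1.42 ± 0.49 (0.372) and Cops7b at -0.89 ± 0.23 (0.155), with Cul4b, a cullin scaffold, at -0.97 ± 0.22 (0.0658). None of these passed, and they were named after their values were seen. These subunits were not a list of their own and were not tested as a set; the list of cullin ligases and the COP9 signalosome had a camera adjusted p of 0.00908, and 0.148 with an estimated correlation. In late cells against T0 the heme enzymes Urod (-1.59 ± 0.27, 0.000122) and Fech (-0.97 ± 0.23, 0.00254) fell, and Alas1, Alad, Uros, Cpox and Ppox did not pass (adjusted p 0.230 to 0.835).

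Without the sparse library, 47 genes passed in the Shank2 sort. Among them Qk stood at -5.55 and Ptbp1 at -4.53, both RNA-binding splicing regulators, Urod at -6.50, and Ep300 at 3.86, all named after their values were seen. In the Mef2d 2% sort without its sparse library 15 passed, Celf1 at 6.26, Srrm4 at 4.05, Ldb1 at 3.10 and Rnps1 at 2.28 among them.

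Chromosomes differed in their share of counts between gates beyond single genes. In the Shank2 sort 1 of 21 chromosome classes was higher in every high gate library than in every low gate library (chromosome 15, by 0.651 on the log2 scale, SD 0.153 and 0.0340) and 4 were lower, where chance gives 0.794% of classes or 0.167. The Mef2d 2% sort had 7 and 5 (chance 2.86%, or 0.6), the Mef2d 30% sort 5 and 3 (0.167) and the Srrm4 sort 7 and 5 (chance 10%, or 2.1).

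For the many genes higher in the Shank2 high gate, a shift of the reporter ratio that the Mef2d reporter shares is a candidate explanation. Of these genes 76.2% lay above 0 in the Mef2d 30% sort (exact 95% interval 67.7 to 83.5), against 49.7% of all genes. Off chromosome 15 it was 55 of 79, or 69.6% (58.2 to 79.5), against 48.8% of all genes there. Both intervals take genes as independent, though genes of a chromosome shifted together. They do not measure the spread between libraries and may be too narrow. Genes with little sgRNA support are among the 122. Random recovery of sgRNAs nearly lost from unsorted cells is argued against by their median late change of -0.0109. The first test of the depth gap between gates and unsorted cells decided nothing: the low gate gave 43 genes without its sparse library and 1 with it. The bounds of 40 and 80 were written before that count was seen, though leaving out the library was chosen after the data were seen. The gap is argued against by the median of the 122 higher genes in the low gate against unsorted cells, -0.265 (95% resampling interval -0.387 to -0.148), and -0.269 (-0.472 to -0.130) for the 79 off chromosome 15.

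The lower median of chromosome 5 genes in the Srrm4 high gate may come from cells that lost the end of the chromosome with the tagged Srrm4. The test argued against this: 683 genes before Srrm4 had a median of -0.146 and 399 beyond it -0.153, a difference of 0.00669 (95% resampling interval -0.0784 to 0.109).

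Other splits of the same libraries were counted by how many gave as many genes. Chance can be excluded for late against T0 (4357 genes, highest other split 4). For the reporter difference, splits that ignore the replicate numbers gave fewer genes (2, 0). So did those among 100 that swap gates within whole pairs (2, 1). In each of these sets 1 split, the real one, reached the count. Splits of the reporter difference remove the gate effect in both lines. They cannot test whether 2 real effects differ, so chance is not excluded there, and the replicate block left 1 gene. In the 10 comparisons of gates, splits that part as many replicate pairs are too few, with a highest other of 0 each. Their real counts were 4, 7, 40 and 1 for Shank2, Mef2d 2%, Mef2d 30% and Srrm4 high against low, and 125 and 1, 4 and 2, and 0 and 4 for the high and low gates of Shank2, Mef2d and Srrm4 against unsorted cells. In the Srrm4 high gate all 4 such splits were as large. Splits that ignore the pairs gave a highest other of 1 in the Mef2d 30% sort and 0 in the rest, with 1 split, the real one, as large outside the Srrm4 high gate (all 10). In the Srrm4 comparisons these 10 splits are too few as well. The replicate block gave 0 genes for Shank2, Mef2d 2% and Srrm4 high against low and for the Shank2 low gate.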
